A study of Homo sapiens with 12 samples.

How the data were processed

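RNA sequencing was analysed for AGS and MKN74, 2 gastric cancer cell lines, each with 1 control and 1 ONECUT2 overexpression library, and samples were grouped by the cell line and genotype labels. The labels describe 12 samples. The 8 ChIP samples among them were not analysed here. Per the labels' protocols, RNA libraries were made with the Illumina TruSeq RNA kit. The submitters' processing notes name hg19, CASAVA 1.7, Bowtie2 2.1.0, HOMER 4.9.1, STAR 2.5.1 and edgeR 3.12.1, with no role or order. The read counter, its annotation and its strand setting are not given in the sources used here. Antisense and overlapping genes, and genes with near-identical copies, are therefore uncertain.

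The authors deposited 1 table of log2 values for the 4 libraries, with 13109 rows named by gene symbol. By the values themselves, each is log2(CPM + 1). Raising 2 to the deposited log2 value and subtracting 1 gives whole multiples of a fixed step in every library, at most 2.6e-08 of a read away from whole for all values, so whole reads were recovered. A read was worth 0.0244 CPM in the AGS control, 0.0231 in AGS overexpression, 0.0239 in the MKN74 control and 0.0218 in MKN74 overexpression. The recovered reads made up 88.1%, 84.4%, 86.4% and 83.1% of the library size implied by that step, so the authors' scaling total was larger than the listed rows. Every row held at least 43 reads in its highest library, and 453, 386, 222 and 166 rows were at 0 in the libraries in the same order, where 0 allows up to 3 reads, or 0.0731, 0.0694, 0.0718 and 0.0654 CPM. 18 rows named by a date instead of a gene, with 0.218% to 0.239% of reads, were left out, which left 13091. Of these, 12951 symbols were found in the reference table by symbol or synonym. Coordinates were not used, since the reference table is of another build than hg19.

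Changes within a line were taken as the difference of the deposited log2 values, among genes with a mean of at least 1 CPM over the line's libraries, and counted at 2-fold. Ratios of CPM have exact (Clopper-Pearson, conditional binomial) intervals at 95%, which cover counting error only, since reads without molecular identifiers are not independent molecules. Overlaps between the lines were set beside the product of the list sizes divided by the number of genes. A limma fit of the log2 values on line and overexpression, with empirical Bayes moderation, a mean trend and Benjamini-Hochberg adjustment at 0.05, used genes with a mean of at least 1 CPM over the 4 libraries and left 1 residual degree of freedom. The cell line pairs the libraries. The unit called for a test on the log scale, and a voom fit of the recovered reads was added after the data were seen.

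The groups, tests, alternatives, 27 gene lists and the rule for naming genes were fixed before the data were examined. For each list the median change of members with a mean of at least 1 CPM was placed among 10000 random lists matched in 20 bins of expression. A list stood apart at a percentile under 2.5 or over 97.5 in both lines in the same direction. Bootstrap intervals resample members. Genes named were ONECUT2 and ACSL5; per line the 8 largest increases and 8 largest decreases with a mean of at least 5 CPM; in both lines the 8 largest each way by the smaller change; the 3 largest in opposite directions each way; the 10 largest line differences each way by the smaller of the differences in the 2 arms; and up to 4 members per list with the largest mean change. Sex-linked marker genes and rows without a gene name were left out, and some genes that the rule takes are not reported here.

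Alternatives were a pseudocount of 2 or 0.1 in place of 1, no filter or a mean of at least 5 CPM, a common median, quantile normalization, recovered library totals, sizes of 1.5-fold and 4-fold, the interval criterion, moderation without trend or robust, and the line left out. A scale of log2(CPM + 1), meant as an alternative, was already the deposited one, so a pseudocount of 2 was used in its place. The interval criterion could not remove a gene, since the filter and the size rule already ensure it at this depth. The pseudocount of 0.1, the recovered totals and voom were added after the data were seen. The limma step and the list step were tested on simulated data. A list of 20 genes planted 0.5 higher reached percentile 100; members that move together were not simulated. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.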

Results

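The study asked what the transcription factor ONECUT2 does in gastric cancer cells, and its title names ACSL5, an enzyme that joins long-chain fatty acids to coenzyme A, as a gene set off by it. RNA sequencing libraries of AGS and MKN74, established human gastric cancer lines, were analysed, with 1 control library and 1 ONECUT2 overexpression library per line. The 8 chromatin immunoprecipitation samples described in the labels were not analysed here. Reads recovered from the deposited values came to 36132888 in the AGS control, 36492454 in AGS overexpression, 36097456 in the MKN74 control and 38110453 in MKN74 overexpression, over 13109 listed rows. With 1 library per group there is no replicate check of a change within a line, so such changes describe these libraries. Levels are in CPM (reads of a gene scaled to a common library size), and a change is the difference of log2(CPM + 1), overexpression minus control, which understates the change of low genes. Intervals on a change or a ratio within a line are at a confidence level of 95% and cover counting error only.

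ONECUT2 transcripts were higher in both overexpression libraries. In AGS its level went from 4.39 to 18.3 CPM, a change of 1.84 and a ratio of 4.18 (interval 3.55 to 4.94). In MKN74 it went from 5.14 to 57.6 CPM, a change of 3.25 and a ratio of 11.2 (9.74 to 12.9). ACSL5 was higher with it in both lines. It went from 8.92 to 45.9 CPM in AGS, a change of 2.24 with a ratio of 5.14 (4.60 to 5.76). In MKN74 ACSL5 went from 0.550 CPM, which rested on 23 reads, to 71.9 CPM, a change of 5.55 with a ratio of 131 (86.9 to 206). Whether reads from the introduced sequence add to the ONECUT2 values is not given in the sources used here.

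**Figure D1:**
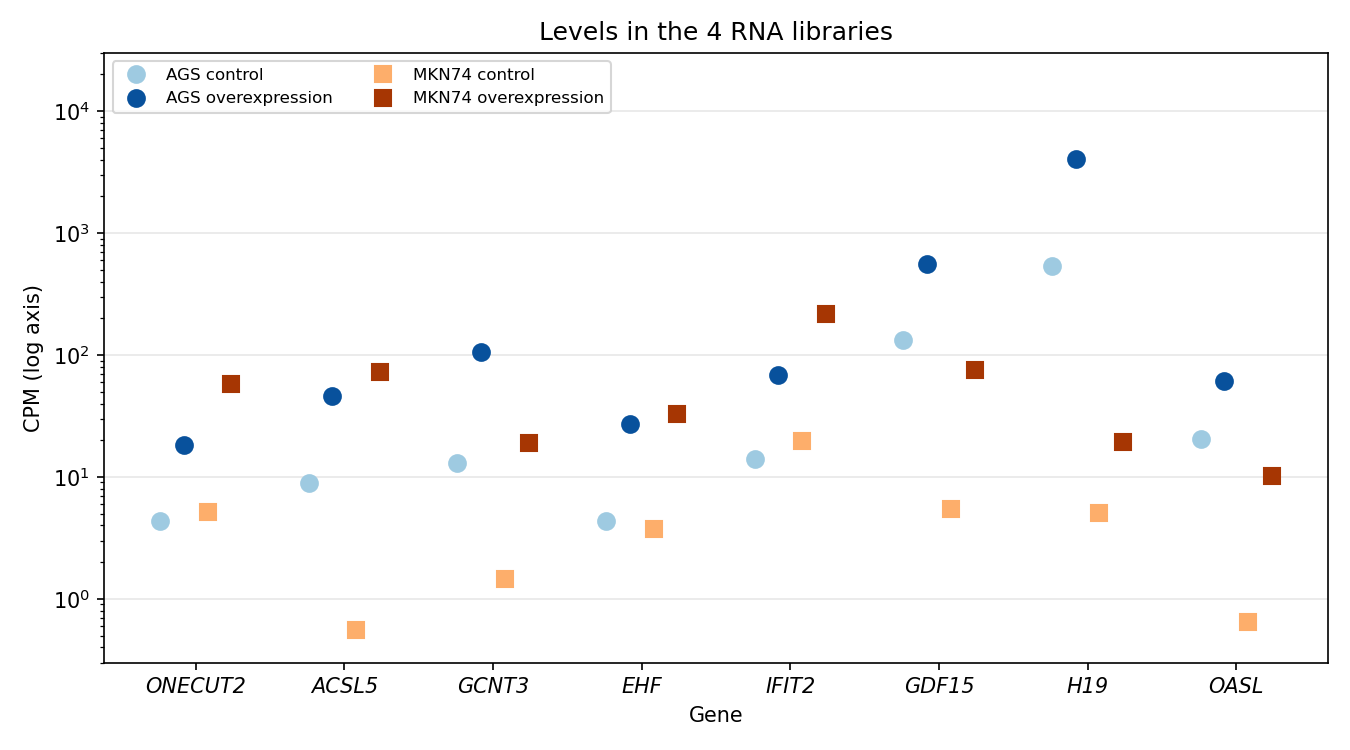
CPM on a log axis (y) of 8 genes (x) in the 4 RNA libraries, 1 point per library, circles for AGS and squares for MKN74, pale for control and dark for overexpression. Every gene shown was at least 2-fold higher on the log2(CPM + 1) scale in the overexpression library of its line, with ACSL5 going from 0.550 to 71.9 CPM in MKN74 and H19 from 533 to 4027 CPM in AGS.

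In the AGS overexpression library 9 of 19 measured genes of the unfolded protein response and amino acid stress were at least 2-fold higher and 0 lower. ASNS, the asparagine synthetase, went from 37.0 to 610 CPM, a change of 4.0. CHAC1, which degrades glutathione, changed by 3.84, PSAT1, an enzyme of serine synthesis, by 2.46, and SLC7A11, the cystine transporter, by 2.82. DDIT4, a stress-induced inhibitor of mTORC1 signalling, changed by 5.22 (13.2 to 528 CPM), and INHBE, an inhibin subunit, by 4.34 (0.195 to 23.2 CPM). ASS1, the argininosuccinate synthase, went from 0.195 to 13.4 CPM. Other large increases included S100P (4.94) and REG3A (3.66, from 0.0980 CPM).

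The largest decreases in AGS were PSG4 (change of -3.12, 15.9 to 0.948 CPM), the nuclear receptor ESRRG (-3.02, 38.0 to 3.79 CPM) and RYR2, a calcium release channel (-2.59). ID3, an inhibitor of helix-loop-helix transcription factors, followed with -2.41, SNCAIP with -2.25, the matrix protein gene THBS1 with -2.07, DPYSL3 with -1.76 and EAF2 with -1.72. PSG4 belongs to a family of near-identical genes, so its level is uncertain.

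In all, 574 of 11675 genes with a mean of at least 1 CPM in AGS changed at least 2-fold, 489 upward and 85 downward, so 85.2% of them were higher. All 574 had a counting interval of the ratio that excluded 1, which the filter and the size rule already ensure at this depth. The median change over the genes was -0.0034 and the standard deviation 0.507. The change within AGS has no replicate check.

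The unfolded protein response and amino acid stress list had a median change of 0.84 in AGS (95% bootstrap interval over members 0.35 to 1.79). That median lay at percentile 100 of 10000 random lists of the same size and expression. ASNS, CHAC1, PSAT1 and the transcription factor gene CEBPB (2.0) were among the 9, whereas HSPA5, an endoplasmic reticulum chaperone chosen after its value was seen, changed by -0.30. Proliferation genes had a median of -0.52 (-0.58 to -0.40; percentile 0) with 0 of 32 past 2-fold, for example CENPE at -0.96, RRM2 at -0.81 and TYMS at -0.79. Nuclear genes of oxidative phosphorylation had a median of -0.41 (percentile 0.010; 0 of 29 past 2-fold), with ATP5A1 at -0.54 and NDUFA4 at -0.65. Cholesterol synthesis genes had a median of -0.34 (percentile 0.040), and 1 of 23 was at least 2-fold lower, IDI1 at -1.11. In the hypoxia and glycolysis list 4 of 19 were higher and 1 lower (median 0.10, percentile 94.0), with SLC2A1, the glucose transporter, at 1.88 and VEGFA at 1.87 beside DDIT4. The housekeeping genes had a median of -0.16 (percentile 37.8) with 1 of 23 past 2-fold, TFRC at -1.25, and GAPDH stood at -0.74 and PPIA at -0.70.

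In MKN74 overexpression all 25 members of the interferon response list were at least 2-fold higher than in the control. IFI44L went from 0.239 to 232 CPM, a change of 7.55 (7.33 to 7.71). OAS2, which senses double-stranded RNA, changed by 6.50, IFI44 by 6.50, the antiviral enzyme gene RSAD2 by 5.56, IFITM1 by 5.50 and OAS1 by 5.33. The list's median change was 3.52 (3.14 to 4.85; percentile 100). In AGS 2 of the 25 were at least 2-fold higher, IFIT2 at 2.21 and OASL at 1.55, and the list median was 0.29 (0.12 to 0.42; percentile 99.9). LGALS3BP (5.17) and ACSL5 (5.55) completed the largest increases in MKN74.

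The largest decreases in MKN74 were SLC7A7, an amino acid transporter subunit (-2.75, 61.9 to 8.33 CPM), the desmosomal cadherins DSG3 (-2.72) and DSG1 (-2.42), and S100A6 (-2.66, 350 to 54.6 CPM). ALPPL2 changed by -2.56, the membrane peptidase gene MME by -2.50, HPGD, which breaks down prostaglandins, by -2.39, and the kallikrein KLK10 by -2.31. ALPPL2 has near-identical paralogs, so its split of reads is uncertain.

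In MKN74 549 of 11914 genes changed at least 2-fold, 388 upward and 161 downward, or 70.7% higher. All 549 had a counting interval that excluded 1, which the filter and the size rule ensure here too. The median change was -0.020 and the standard deviation 0.529. Requiring a mean of 5 CPM left 347 genes.

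Among other lists in MKN74, 2 of 9 measured ONECUT and hepatic or intestinal transcription factors were higher and 1 lower (median -0.32, percentile 0.290). ONECUT2 was among the higher ones, and the lower one was SOX9 (-1.67). The bootstrap interval of the MKN74 median over members was -0.56 to 3.25. Its percentile was 2.6 after quantile normalization and 2.9 at a mean of at least 5 CPM. In AGS the median of that list was 0.081 (percentile 70.2; -0.11 after quantile normalization). Acyl-CoA synthetases and fatty acid transporters had a median of 0.20 in MKN74 (percentile 99.2) with 2 of 16 higher, ACSL5 and ACSM3 (2.65), and 0.22 in AGS (percentile 96.0) with 2 of 16 higher, ACSL5 and SLC27A1 (1.89). Beta-oxidation genes had medians of 0.18 in MKN74 (percentile 99.9) and 0.022 in AGS (percentile 74.2; -0.014 after shifting to a common median), with 0 past 2-fold in either line. Fatty acid synthesis genes had medians of -0.12 and -0.14 (percentiles 11.2 and 23.4), and 1 was at least 2-fold higher, DGAT2 in MKN74 at 1.03. With a pseudocount of 2, with quantile normalization and at a mean of at least 5 CPM, 0 of them were higher in MKN74. Cholesterol synthesis genes had a median of 0.17 in MKN74 (percentile 100, to the nearest whole number).

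Among genes with higher levels in both overexpression libraries, GCNT3, which builds mucin core glycans, changed by 2.92 in AGS and 3.02 in MKN74. EHF, an epithelial ETS transcription factor, changed by 2.40 and 2.83. IFIT2 changed by 2.21 and 3.40, GDF15, a stress-induced cytokine, by 2.08 and 3.55, the noncoding RNA H19 by 2.91 and 1.73, and OASL by 1.55 and 2.75. SLC9A2, a sodium and proton exchanger, was lower in both, at -1.05 and -1.42. Smaller decreases shared by the lines, none past 2-fold in both, were those of LINC00641 (-0.91 and -0.81), MYO10 (-0.80 and -0.79), DSC2 (-0.77 and -0.82), CDK2AP1 (-0.83 and -0.74), CTSV (-0.67 and -0.89), DNTTIP2 (-0.67 and -0.79) and GLMN (-0.65 and -0.68).

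Of 10766 genes with a mean of at least 1 CPM in each line, 37 were at least 2-fold higher in both, against 8.47 for independent lists of these sizes, and 1 was lower in both, against 0.460. Opposite directions were in excess as well. Higher in AGS and lower in MKN74 were 25 genes, against 3.30, led by HPGD, EMP1 and ABCC3, and lower in AGS and higher in MKN74 were 5, against 1.18, led by ID2, PCDH7 and THBS1. Across these genes, which are not independent replicates, Pearson's r of the changes was 0.0873 and Spearman's rho 0.138, and 56.7% had the same sign. Each line had its own control, so no library is shared between the 2 sets of changes. The 38 genes of the same direction became 21 or 60 with another pseudocount and 20 at a mean of at least 5 CPM.

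**Figure D2:**
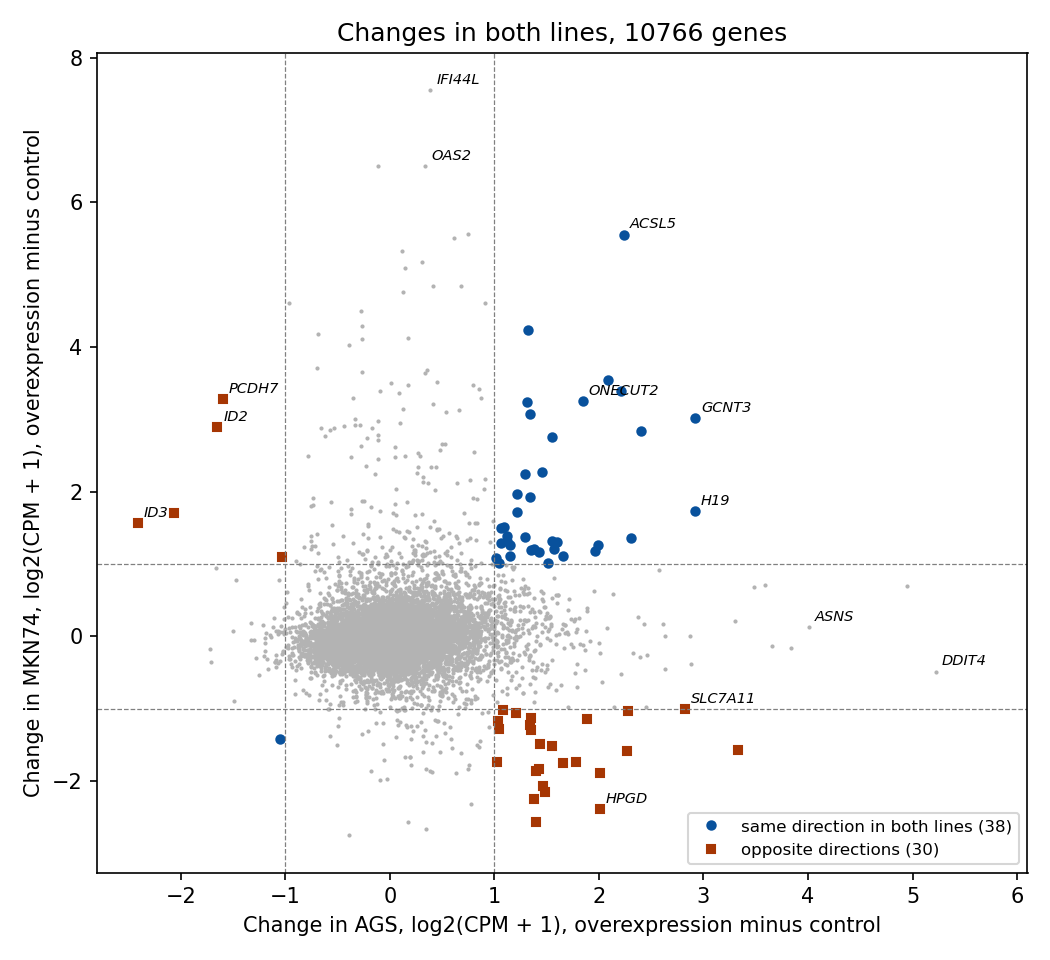
Change in AGS (x) against change in MKN74 (y), both as differences of log2(CPM + 1), for 10766 genes, 1 point per gene, with dashed lines at a 2-fold change. The 38 genes past 2-fold in the same direction are circles and the 30 in opposite directions squares, and the interferon genes IFI44L and OAS2 lie high on y near 0 on x.

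Taking the lines as replicates, no gene passed the test of an overexpression effect common to both. GCNT3 came nearest, with a common change of 2.97 (SE 0.18) in limma and a Benjamini-Hochberg adjusted p of 0.488. ONECUT2 had 2.55 (SE 0.38) and ACSL5 3.90 (SE 0.81), each with a limma adjusted p of 0.8. limma called 0 of 12340 genes, 566 had an unadjusted p under 0.05, and with voom weights 0 were called and 902 had one. Without any effect a share of 0.05 of the genes would be under that threshold. The 566 lie below that share and the 902 above it. Adjusted over the list alone, limma called ONECUT2 among the transcription factors (adjusted p = 0.0267, both lines higher), GDF15 among p53 targets (0.026), EHF among epithelial genes (0.0038), and IFIT2 and OASL among interferon genes (smallest 0.0147). Adjusted over the list alone, 0 genes of the remaining lists were called. These adjustments were not corrected across the 27 lists, and over all genes the limma adjusted p of each gene so called was 0.8. ONECUT2 is itself the gene that was overexpressed. The fit leaves 1 residual degree of freedom. On simulated libraries with a spread of 0.2 log2 between them, the same fit recovered 92.8% of 2-fold changes and 100% of 4-fold changes, and made a mean of 13.4 false calls per run beside 200 changed genes. Those changes were planted at the same size in both lines. In the data the lines differed more, with a standard deviation of the change of 0.507 in AGS and 0.529 in MKN74 and an r of 0.0873. The simulated rates therefore do not give the power of this fit, and 0 calls do not exclude common changes.

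The p53 targets had medians of 0.34 in AGS and 0.34 in MKN74, both at percentile 100. At least 2-fold higher were 4 of 21 in AGS, among them SESN2 (1.47) and BBC3 (1.35), and 3 of 22 in MKN74, among them the death receptor gene FAS (3.64), with GDF15 in both. Ribosomal protein genes had small medians of 0.052 and 0.062 (percentiles 99.5 and 100), with 0 of 33 past 2-fold in either line, RPL13 at 0.62 and 0.14 and RPL5 at 0.05 and -0.62. Immediate-early genes had medians of 0.35 and 0.080 (percentiles 100 and 98.4), with 4 of 28 higher in AGS, KLF2 (1.73) and FOS (1.19) among them, and 0 of 27 higher and 1 lower in MKN74. JUN was at 0.59 and 0.95. WNT/beta-catenin targets had medians of 0.31 and 0.12 (percentiles 99.8 and 98.5), with SP5 at 1.20 in AGS and EPHB2 at 1.32 in MKN74, with 1 of 15 higher and 0 lower in AGS and 2 of 16 higher and 1 lower in MKN74. The median of the WNT list in MKN74 was -0.035 at a mean of at least 5 CPM. Intestinal epithelium genes had medians of 0.45 and 1.36 (percentiles 99.4 and 100), with 1 of 9 and 3 of 5 higher, MUC13 at 0.45 and 1.49, and CDX2 at 0.10 and -0.32. That list had a median of -0.32 in MKN74 at a mean of at least 5 CPM. Neuroendocrine and neuronal genes had medians of -1.05 and -0.33 (percentiles 0.395 and 1.08), but the AGS value rests on 1 gene, TUBB3. These lists and the interferon list, 7 in all, stood apart in the same direction in both lines, and 27 lists had been fixed. Other lists passed these percentiles in a single line, such as proliferation in AGS and beta-oxidation in MKN74. Some lists would therefore coincide even if the lines were unrelated, and how many was not computed. Bootstrap intervals over members included 0 for the intestinal list in AGS (-0.67 to 0.98) and MKN74 (-0.385 to 1.78), the WNT list in AGS (-0.0018 to 0.47) and MKN74 (-0.17 to 0.57), and in MKN74 also for the immediate-early (-0.13 to 0.34) and neuroendocrine (-0.95 to 0.76) lists. With quantile normalization the immediate-early, intestinal and neuroendocrine lists no longer stood apart. At a mean of at least 5 CPM 3 of the 7 still stood apart, the interferon, p53 and ribosomal lists.

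Proliferation genes had a median of -0.14 in MKN74 (percentile 8.20) and oxidative phosphorylation genes 0.0145 (percentile 97.6; -0.0055 after shifting to a common median), with 0 members past 2-fold in either list. The unfolded protein response and amino acid stress list had a median of 0.067 there (percentile 95.4), with 0 of 21 higher and 1 lower, SLC7A11 at -1.01, and a percentile of 98.1 after quantile normalization. Histone genes had medians of -0.57 in AGS and 0.69 in MKN74 (percentiles 0.060 and 99.5), with 0 of 6 lower and 3 of 7 higher, HIST1H1C at -0.82 and 1.23. Their transcripts are mostly not polyadenylated and share sequence, so these levels are uncertain. In the list of TGF-beta and BMP targets the members split in each line, with 3 of 18 higher and 5 lower in AGS (median 0.079, percentile 82.6) and 3 of 18 higher and 2 lower in MKN74 (median -0.060, percentile 32.9). ID2 and ID3 were at -1.65 and -2.41 in AGS and at 2.90 and 1.57 in MKN74. Mesenchymal genes had medians of 0.39 and 0.70 (percentiles 97.2 and 100), with 3 of 11 higher and 2 lower in AGS and 3 of 10 higher in MKN74, AXL at 1.32 and 0.67, and this list stood apart in both lines with a pseudocount of 2, with quantile normalization and at a mean of at least 5 CPM. Epithelial genes had medians of 0.16 and 0.0052 (percentiles 99.1 and 81.3; -0.015 in MKN74 after shifting to a common median), with 1 of 26 and 3 of 27 higher.

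Gastric epithelium genes had a median of 0.039 in AGS (percentile 51.2; 1 of 7 higher and 2 lower), and in MKN74 1 gene was measured, MUC1 at 0.63 (percentile 89.2). NRF2 targets had medians of 0.048 and -0.071 (percentiles 84.6 and 39.5), with 2 of 17 higher in AGS and 1 higher and 3 lower of 19 in MKN74, GCLM at -1.02 there. NF-kB targets and cytokines had medians of 0.14 and -0.0022 (percentiles 78.4 and 39.7; -0.033 in AGS after quantile normalization), with 1 of 16 higher in AGS, PTGS2 at 1.16, and 3 of 14 higher and 1 lower in MKN74, CXCL8 at 1.22. At a mean of at least 5 CPM the MKN74 median of that list was -0.23 (percentile 1.96), with 0 higher and 1 lower. The hypoxia list had a median of 0.073 in MKN74 (percentile 94.7; 2 of 19 higher, EGLN3 at 2.95) and the housekeeping list -0.030 (percentile 73.8; 0.013 after quantile normalization; B2M at 1.15). Immune cell markers had medians of -0.20 and 0.24 (percentiles 6.20 and 82.5), with 0 of 6 and 1 of 4 past 2-fold, and medians of 0.33 and -0.083 at a mean of at least 5 CPM. Fibroblast and endothelial markers had medians of 0.13 and 0.99 (percentiles 60.5 and 99.3), with 0 of 3 and 1 of 3 past 2-fold, ACTA2 at 3.10 in MKN74, and the AGS median was -0.27 at a mean of at least 5 CPM. Of the mitochondrially encoded transcripts 0 were listed.

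**Figure D3:**
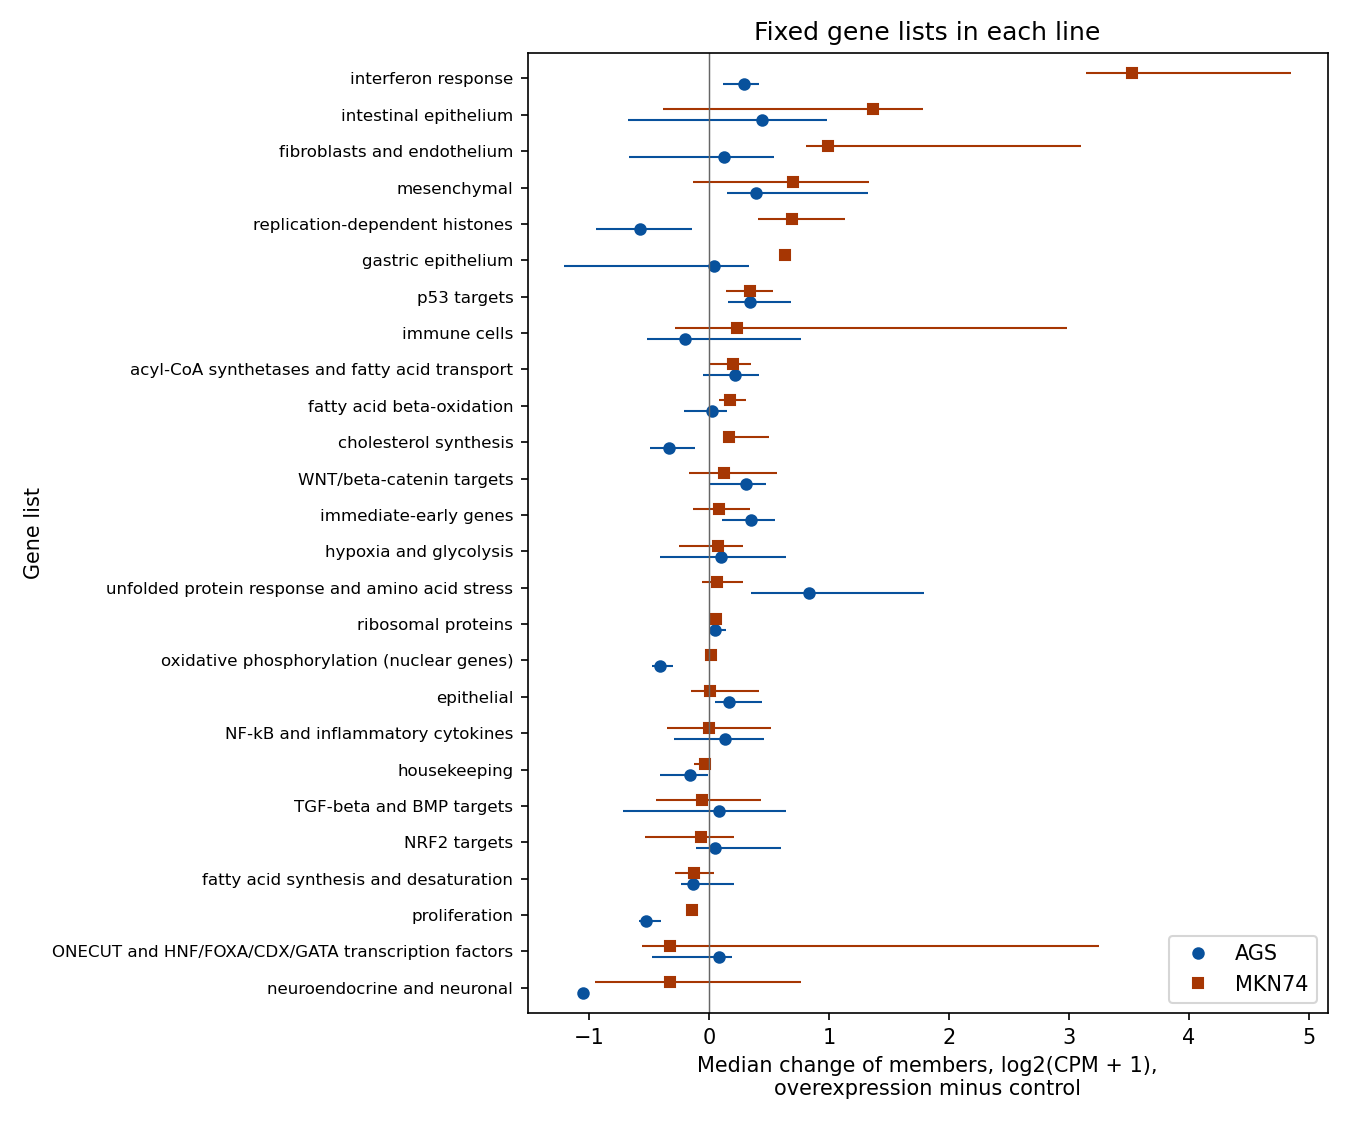
Median change of the members of each fixed gene list (y), as a difference of log2(CPM + 1) (x), circles for AGS and squares for MKN74, with lines for the 95% bootstrap interval over members. The interferon response list lies at 3.52 in MKN74 and 0.29 in AGS. The unfolded protein response and amino acid stress list lies at 0.84 in AGS and 0.067 in MKN74. Points without a line rest on 1 gene or have an interval narrower than the point.

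Gastric and intestinal transcripts were higher in AGS than in MKN74, at 6 of 6 and 6 of 8 measured list members by limma. LYZ, the lysozyme gene, stood at 7661 and 7066 CPM in the AGS libraries and at 0 and 6.89 CPM in MKN74, and CTSE, the gastric protease cathepsin E, at 1394 and 1433 CPM against 0.0480 and 0.262 CPM. PAGE4, LDHB, PLA2G2A, GALC, TSPAN8, MSN, VTN and MMP14 were also among the largest differences toward AGS, with limma estimates from -9.91 for PAGE4 to -8.06 for MMP14. Among the largest differences toward MKN74 were the keratin genes KRT6A, at 4291 and 1495 CPM against 1.56 and 6.52 CPM in AGS, and KRT5, at 169 and 475 CPM against 0 and 0.0460 CPM. KRT6A shares sequence with close paralogs. BMP7 (8.56, SE 0.18), RDX (7.99), ME1 (7.53), FSCN1 (7.53), A4GALT (7.41), PFN2 (7.39), SCRN1 (7.33) and the cadherin gene CDH3 (7.20) were higher in MKN74.

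limma called 5330 of 12340 genes for the line at a Benjamini-Hochberg adjusted p under 0.05, 2582 higher in MKN74 and 2748 higher in AGS. In both arms 1319 genes were at least 2-fold higher in MKN74 and 1593 at least 2-fold higher in AGS. Of the 20 genes named here the limma adjusted p was at most 0.00226 (KRT6A). Of the measured list members, 11 of 15 ONECUT and related transcription factors were higher in AGS and 0 in MKN74, and 16 of 23 p53 targets were higher in AGS and 2 in MKN74. Of 32 proliferation genes 9 were higher in MKN74, 1 was higher in AGS and 22 were not called, and of 19 NRF2 targets 8 were higher in MKN74, 2 were higher in AGS and 9 were not called. The 1 residual degree of freedom is the difference between the lines in their change with overexpression. These p-values weigh the line difference against that disagreement, moderated across genes. Nothing in the labels says how the cultures relate, so they do not measure a spread between independent cultures of a line.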

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

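Of the tests below, the centring of changes by expression level was written before its result was seen, and the others were chosen after the result each measures had been seen. The lines moved in opposite directions at the following results, apart from oxidative phosphorylation, and none of these differences was tested, since each line has 1 library per arm. Lower in AGS and higher in MKN74 were ID3 (-2.41 and 1.57), THBS1 (-2.07 and 1.7), ID2 (-1.65 and 2.90) and PCDH7 (-1.60 and 3.28). Higher in AGS and lower in MKN74 were ALPPL2 (1.39 and -2.56), HPGD (2.01 and -2.39), EMP1 (2.01 and -1.89), ABCC3 (1.78 and -1.74), KRT6A (1.55 and -1.52) and SLC7A11 (2.82 and -1.01). By list median, cholesterol synthesis stood at -0.335 in AGS and 0.168 in MKN74, and replication-dependent histones at -0.574 and 0.690. Oxidative phosphorylation stood at -0.410 in AGS and 0.0145 in MKN74. The MKN74 bootstrap interval over members was -0.0231 to 0.0449, so a rise there is not shown. The median of oxidative phosphorylation in MKN74 was -0.0055 after shifting to a common median.

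Interferon response genes were 3.52 higher at the median in the MKN74 overexpression library. RNA of AGS cells in that library is argued against, since 37 transcripts abundant in AGS and near 0 in the MKN74 control lay at a median of 0.0189% of their AGS level, against 0.0175% in the control, whereas the interferon genes' rise would need 347% of the AGS level at the median. Scaling is argued against by a list median of at least 3.5 under a common median and quantile normalization. An equal log2 change in both lines from the overexpression procedure is argued against by the AGS median of 0.29. Its upper bound of 0.42 lies below the MKN74 lower bound of 3.14, but these bounds resample members, not cultures. A procedure effect that was smaller in AGS because of its starting levels was not tested and stays open. Among named members, the AGS control stood above the MKN74 control for OAS2 (21.7 and 0.55 CPM), OAS1 (42.8 and 5.12 CPM) and IFI44L (3.29 and 0.239 CPM). IFIT2 went the other way. What stays open, untested, is whether ONECUT2 itself or a response of MKN74 to the introduced material raised these genes. Another difference between the control and overexpression cultures stays open as well, since 1 library per arm holds all of these.

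Genes of the unfolded protein response and amino acid stress list were 0.84 higher at the median in the AGS overexpression library. RNA of MKN74 cells is argued against by 24 transcripts abundant in MKN74 and near 0 in the AGS control. They lay at a median of 0.0646% of their MKN74 level, against 0.0469% in the control. The 14 list members that rose would need 151% at the median, and 9 of them over 100%, which no mixing could give. Scaling is argued against by a list median of 0.88, at percentile 100, under quantile normalization. Under a common median the list median was 0.80, but its percentile could not change, since all genes of a library shift alike. A slower growing or nutrient-limited culture at harvest cannot be told apart from an effect of ONECUT2, since each arm is 1 culture, and the proliferation list stood at -0.52 in the same library.

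More genes were higher than lower at 2-fold, at 85.2% in AGS and 70.7% in MKN74. Scaling as the whole cause is argued against by a share of at least 62.5% in either line under a common median, quantile normalization and recovered totals. The change did fall with expression level, from 0.18 in the lowest 5 of 20 bins to -0.13 in the highest in AGS, but after centring each bin the share was still at least 68.2%. Genes near the detection limit as the whole cause are argued against by a share of at least 65.7% at a mean of at least 5 CPM. The biological explanation, an effect of ONECUT2, was not tested apart from the culture.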

How the results depend on the processing

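Of the tests here, the pseudocount of 0.1, recovered totals and voom weights were chosen after the data were seen. The count of genes changed the same way in both lines was 21 with a pseudocount of 2, 60 with 0.1, 20 at a mean of at least 5 CPM, 166 at 1.5-fold and 5 at 4-fold, against 38, and its ratio to independent lists ran from 2.21 to 14.6. Genes changed in opposite directions numbered 131 at 1.5-fold (ratio 1.96) and 1 at 4-fold (ratio 19.8), against 30, and 21 to 38 in the other settings. Changed genes numbered 1982 in AGS and 1318 in MKN74 at 1.5-fold (66.2% and 59.7% higher), 71 and 144 at 4-fold (90.1% and 90.3%), and 347 in MKN74 at a mean of at least 5 CPM. These follow from the size or filter itself. The changes in MKN74 of ONECUT2 (3.06 with a pseudocount of 2 and 3.46 with 0.1) and ACSL5 (4.86 and 6.79) kept their direction. Lists standing apart numbered 4 at a mean of at least 5 CPM, 3 of them shared with the 7. There the medians in MKN74 of intestinal epithelium (-0.322) and WNT targets (-0.0349) reversed because fewer members were left. Interferon response, p53 targets and ribosomal proteins stood apart in each of the alternatives run for lists. These were both pseudocounts, a common median, quantile normalization and a mean of at least 5 CPM. A common median shifts all genes of a library alike, so it could not change a percentile. Quantile normalization gave 6 lists, 4 of them shared. It added the mesenchymal list and the unfolded protein response and amino acid stress list. The mesenchymal list was also added at a mean of at least 5 CPM and with a pseudocount of 2 (8 lists). The median of oxidative phosphorylation in MKN74 reversed to -0.0055 with a common median. Among single named genes 1147 values stayed within their counting interval and 343 moved beyond it. Of the changes of at least 2-fold 0 reversed, and smaller changes were not checked for a reversal. limma called 0 genes for overexpression in all 10 settings, with 12 (no replicate block, the line left out) to 902 (voom) at an unadjusted p under 0.05, and 4386 to 5676 genes for the line in its 9 settings. No scaling moved the share of higher calls by over 10 percentage points (lowest 77.3% in AGS and 62.5% in MKN74, both by quantile normalization). Leaving out a library was not run, since it leaves 0 residual degrees of freedom. Depth limits ratios of genes near 0, where 3 reads are at most 0.0731 CPM.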

Other observations

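The following gene groups were put together after the values had been seen, so their percentiles describe and do not test. In AGS, 8 of 11 amino acid transporter genes were at least 2-fold higher (median 1.22), among them SLC6A9 at 2.89, SLC43A1 at 2.55 and SLC7A5 at 1.37, whereas the median in MKN74 was -0.29. Of the 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs for translation, 6 were at least 2-fold higher in AGS and 0 in MKN74. CARS at 1.67 and GARS at 1.55 in AGS were among them. The median of the 20 was 0.54 in AGS (bootstrap interval over members -0.21 to 1.07, percentile 100) and -0.12 in MKN74. The 17 mitochondrial synthetase genes had medians of -0.24 and -0.070. The 8 genes of the cytosolic chaperonin had a median of -0.58 in AGS and -0.040 in MKN74. S100 genes had medians of 0.62 and -0.27, with S100P at 4.94 and S100A9 at 2.39 in AGS and S100A6 at -2.66 in MKN74.

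In MKN74, 6 of 9 tissue kallikrein genes were at least 2-fold lower (median -1.15), KLK10 at -2.31 and KLK14 at -2.16 among them, whereas 3 of 7 were at least 2-fold higher in AGS (median 0.86), KLK8 at 1.88 among them. Desmosome and cornified envelope genes had 9 of 24 lower and 1 higher in MKN74 (median -0.61), with DSG3 at -2.72 and KRT13 at -2.25 but KRT5 at 1.49, and 4 of 14 higher in AGS (median 0.26). Genes of class I antigen presentation had 7 of 12 higher in MKN74 (median 1.22), among them TAP1 at 2.04, HLA-B at 2.04, NLRC5 at 1.69 and B2M at 1.15, and 2 of 15 in AGS (median 0.059). HLA genes share sequence, so their levels are uncertain.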
